A study of Mus musculus with 6 samples.

How the data were processed

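The series holds 6 arrays, 1 per group, for chow, fast-food diet and fast-food diet with canertinib at 2 and at 5 months. Per the labels, biotinylated cRNA was made from total RNA and each array received RNA pooled from 3 to 4 livers. Per the submitters' processing notes the deposited values are MAS5 signals, for which the version is not given in the sources used here. The deposited intensity values are on a linear scale, and from the values each array had been scaled by the authors so that its mean without the lowest and highest 2% of probe sets is 500. Microarray signals have no read depth, and precision is limited by the number of arrays and, for dim genes, by the floor.

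Of 45101 probe sets, 34958 were listed with 1 gene symbol in the platform annotation used here, 932 with several and 9211 with none, and 64 of all were control probe sets. Each gene was represented by the probe set with 1 symbol that had the highest mean signal over the 6 arrays. Signals were raised to a floor of 221.4, the 50th percentile of all values, and log2 transformed, and 13989 of 18194 genes were above the floor on at least 1 array and formed the measured set. A gene at the floor on 1 of the arrays compared is given as at least N-fold, or as a bound on the log2 scale.

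Comparisons were diet against chow, drug with diet against diet, and drug with diet against chow, each at 2 and at 5 months, and 5-month chow against 2-month chow as background. The planned comparisons were of single arrays and carried no test. Added after seeing the data, a limma fit with the log2 signals of all 6 arrays, terms for treatment and study and a variance trend on mean signal left 2 residual degrees of freedom, and counts of genes at a Benjamini-Hochberg adjusted p under 0.05 were taken from it. Its error contains any difference of an effect between the studies. Genes at least 2-fold different were counted, and counts shared between 2 comparisons are given beside n1 times n2 over N, the number independent lists would share. For 34 gene lists on metabolism, cell types and signalling, 7 of them named as core lists, the median log2 change was set against 10000 random lists of the same size drawn from 20 bins of mean signal. Chance would put 5.0% of lists outside the limits, or 6.8 of the 136 medians of the 4 diet and drug comparisons, and 69 lay outside. Of the 34 medians of the chow pair, without diet or drug, 6 lay outside where chance would put 1.7. An excess over chance is therefore not by itself an effect of diet or drug. For comparisons that share the fast-food array, unchanged groups were simulated 100 times.

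Before the data were examined, the groups, lists, floor, thresholds, alternatives and the rule for named genes were fixed. Named were the 8 genes with the largest rise and the 8 with the largest fall at both times, ranked by the smaller change and above the floor on all arrays, the 4 largest rises and falls at each single time, the 4 members of each list with the largest mean change, and 11 genes always named where measured. Genes outside the rule are said to be so. The alternatives were quantile, loess and median normalization, floors at the 40th and 60th percentile or none, genes above the floor on all arrays, the mean over the probe sets of a gene, probe sets with _s_at, _x_at or _a_at endings left out, thresholds of 1.5-fold and 3-fold, unmatched random lists, and the mean in place of the median. Genes that differ between the chow arrays were left out as an alternative added after seeing the data. The alternatives for lists of the drug-treated liver against chow were run after seeing the data too. Some listed genes were not analysed here.

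The procedure was tested on simulated data for the diet comparison at 2 months, with 12765 genes and 10 runs. Of simulated changed genes, 10.8% were called at 1.5-fold, 43.4% at 2-fold, 78.5% at 3-fold and 82.8% at 4-fold, and 1.67% of unchanged genes were called. Between the real chow arrays, 2.60% of measured genes were at least 2-fold different. Unchanged lists stood apart in 5.1% of cases, and lists of 20 genes shifted by 0.5 log2 stood apart in 10 of 10 runs. With 4-fold changes present in both simulated studies, limma called 77.9% of changed genes, and unchanged genes made up 0.1% of its calls. Each simulated change was the same in both studies, and noise was independent between genes. These shares therefore need not hold for the real calls, where effects can differ between the studies. Analyses used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1, and figures were drawn with matplotlib 3.10.9.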

Results

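Liver RNA of male C57BL6/J mice, an inbred laboratory strain, was measured on Affymetrix Mouse Genome 430 2.0 arrays, on which sets of short probes report the transcript level of a gene as a fluorescence signal. There were 6 groups with 1 array each, and the RNA on each array was pooled from 3 to 4 livers. Mice aged 6 to 8 weeks at the start received chow, a fast-food diet, or the fast-food diet together with canertinib, in a 2-month and in a 5-month study. Canertinib is an irreversible inhibitor of the ERBB receptor kinases, among them the epidermal growth factor receptor EGFR. The fast-food diet held 21% fat and 34% sucrose by weight and 0.2% cholesterol, and glucose and fructose were added to the drinking water. The drug was mixed into the food throughout the 2-month study at an estimated 80 mg/kg per day. In the 5-month study it was injected at 80 mg/kg on 5 days per week over the final 5 weeks, and the fast-food group received vehicle injections. Route, duration of treatment and length of study therefore differed together between the 2 times. The labels name no injection for the 5-month chow group, so comparisons with chow at 5 months do not separate diet and injection.

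Each group was 1 array, so no difference within a study had a replicate check or a significance test, sizes are given without an error, and the number of arrays limits the precision. A limma fit over all 6 arrays, with the study as a block, was added after the data were seen. It takes the studies as repeats of each other, although route and duration of the drug differed between them and only the 5-month fast-food groups are labelled as injected. The background was the pair of chow arrays, between which 179 genes were at least 2-fold higher and 185 at least 2-fold lower at 5 months than at 2 months, out of 13989 measured genes. Between 84.3% and 86.6% of the measured genes lay above the floor on each of the 6 arrays. Relative to the 2-month chow array, the spiked control transcripts had a mean log2 signal of 0.32 on the fast-food array and 0.48 on the drug array of the 2-month study. In the 5-month study the corresponding values were 0.19 for chow, -0.20 for fast food and 0.21 for the drug. A gene list was said to stand apart when its median log2 change lay among the lowest or highest 2.5% of 10000 random lists matched on signal, which describes these arrays and is not a test of the diets.

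The first question was how the liver transcriptome differed between fast-food feeding and chow. At both times the fast-food liver held more transcript of genes for lipid storage, lipogenesis, extracellular matrix and macrophages, and less of genes for cholesterol synthesis and of male-biased liver genes. Apoa4, which encodes an apolipoprotein of triglyceride-rich lipoproteins, was 22.6-fold higher at 2 months and 14.9-fold higher at 5 months. Ranked by the smaller of the changes at the 2 times, the isoprenoid and sterol synthesis gene Idi1 led the lower genes, with log2 changes of -2.81 and -3.82. Egfr, the gene of the receptor that canertinib inhibits, was also lower, with log2 changes of -1.42 and -2.36, and 5 and 6 of its 6 probe sets had that sign.

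The lipid droplet and PPARgamma target list had a median log2 change of 1.16 at 2 months and 0.90 at 5 months and stood apart at both times. Of its 16 measured members, 9 and then 7 were at least 2-fold higher and none was at least 2-fold lower. The fatty acid uptake gene Cd36 had log2 changes of 2.17 and 2.29, and Cidec, whose product coats lipid droplets, was at least 3.89-fold and at least 9.57-fold higher, its signal being at the floor on both chow arrays. Pparg itself was at least 1.63-fold higher at 2 months and 1.85-fold higher at 5 months. De novo lipogenesis genes had medians of 0.59 and 0.24, with 7 and then 5 of 21 members at least 2-fold higher and 0 and then 1 at least 2-fold lower. Fatty acid synthase, Fasn, was 2.82-fold and 2.04-fold higher, the elongase gene Elovl6 had 1.07 and 1.15, and the lipogenic transcription factor gene Srebf1 had 1.12 and 0.69, whereas the stearoyl-CoA desaturase gene Scd1 had 0.41 and -0.02. Cholesterol biosynthesis genes stood apart on the lower side with medians of -0.77 and -1.22, and 6 and then 12 of 20 members were at least 2-fold lower with none at least 2-fold higher. Sqle and Msmo1, which encode enzymes of the sterol pathway, had log2 changes of -1.20 and -2.28 at 2 months and -2.54 and -3.28 at 5 months. Between the chow arrays the cholesterol list was shifted by 0.26, higher at 5 months, and stood apart.

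Macrophage and inflammation genes had medians of 0.80 and 1.31, and 11 and then 19 of 29 members were at least 2-fold higher, with 0 and then 1 at least 2-fold lower. Within this list Lgals3, the galectin of activated macrophages, had log2 changes of 1.56 and 2.99, and the antigen presentation gene Cd74 had 1.10 and 2.42. Markers of resident Kupffer cells, the macrophages of the liver sinusoids, had medians of 0.41 and 0.58. In any amount, 9 and then 7 of the 12 markers were higher and 3 and then 5 were lower. At each time 4 were at least 2-fold higher, among them the complement gene C1qa, which was 4.47-fold and 5.64-fold higher. Extracellular matrix genes had medians of 0.62 and 0.89, with 7 and then 11 of 26 members at least 2-fold higher and none at least 2-fold lower. The fibrillar collagen gene Col3a1 had log2 changes of 1.81 and 2.79 and Sparc had 1.33 and 2.68, while Col1a1 was at least 3.47-fold and at least 4.82-fold higher. Beside them, stellate cell markers had medians of 0.23 and 0.61 and endothelial markers 0.22 and 0.35, and interferon response genes had 0.41 and 0.45 with 0 and then 1 of 14 at least 2-fold higher. Between the chow arrays the matrix list was shifted by -0.22, lower at 5 months, and stood apart.

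Male-biased liver genes, which depend on the pulsatile growth hormone pattern of males, had medians of -0.45 at 2 months and -1.63 at 5 months, and 4 and then 12 of 15 were at least 2-fold lower. Between the chow arrays this list was shifted by 0.24, higher at 5 months, and stood apart. Hsd3b5, a steroid-metabolising enzyme gene of male liver, had a log2 change of -3.40 at 2 months and was at the floor at 5 months with a bound of -5.73, and the oxysterol hydroxylase gene Cyp7b1 had -2.63 and -3.57. Female-biased genes had medians of 0.75, which stood apart, and 0.21, which did not, with 3 and then 2 of 8 members at least 2-fold higher. Fatty acid oxidation genes stood apart at 5 months with a median of 0.33 and not at 2 months with 0.17. Glycolysis and fructose metabolism genes likewise had 0.36 and 0.21, and 3 and then 2 of 17 members were at least 2-fold higher at 5 and at 2 months. NRF2 targets had medians of 0.36 and 0.23 and stood apart at both times. Of 15 members, 2 and then 3 were at least 2-fold higher and 1 was at least 2-fold lower at each time. Lists that stood apart at 2 months alone were acute phase genes with 0.37, lipoprotein genes with 0.32, circadian clock genes with -0.32 and ribosomal protein genes with -0.27, and their 5-month medians were -0.06, -0.04, -0.16 and -0.05. Those apart at 5 months alone were bile acid genes with -0.61, hepatocyte identity genes with -0.38, p53 response genes with 0.46 and cell cycle genes with 0.24, against 0.09, 0.03, 0.17 and 0.00 at 2 months. Of these lists, acute phase, bile acid and ribosomal genes also stood apart between the chow arrays, with shifts of 0.37, 0.31 and -0.08, and Saa1 differed by 3.38.

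In all, 277 genes were at least 2-fold higher and 217 at least 2-fold lower with the diet at 2 months, and 381 and 256 at 5 months. The times, which share no array, had 105 higher genes in common where independent lists would have 7.5, and 40 lower genes where they would have 4.0. In the fit over both studies, limma called 4 genes at an adjusted p under 0.05 with the diet, Apoa4, C1qa, S100a10 and Sirpa, all higher, and the other 141 shared genes were not called. Other genes with large and like differences were Ly6d with 2.76 and 3.72, the tubulin gene Tubb2a with 3.40 and 2.59, Sirpa with 2.41 and 2.21, 2010003K11Rik with 2.14 and 2.63 and S100a10 with 2.02 and 1.94. On the lower side they were the coactivator gene Ppargc1b with -2.65 and -3.13, the carboxylesterase gene Ces2a with -1.89 and -2.00, Osgin1 with -2.07 and -1.95, the cytokine receptor gene Lifr with -1.86 and -2.57 and the complement gene C8b with -1.58 and -2.98. Some list calls ended under other settings, namely stellate markers at 2 months under 6 of 12 alternatives, endothelial markers under 3 at 2 months and 1 at 5 months, lipoprotein genes under 2 (quantile and loess normalization), and under 1 each NRF2 targets, acute phase, circadian and ribosomal genes at 2 months and cell cycle genes at 5 months. Other lists came to stand apart, at 2 months glycolysis genes under 3 alternatives, cholangiocyte markers under 2, and fatty acid oxidation, ERBB, T and NK cell, adipose, bile acid and p53 lists under 1 each. At 5 months they were female-biased genes under 4, gluconeogenesis and xenobiotic genes under 3 each, and acute phase, adipose and lipoprotein lists under 1 each.

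**Figure D1:**
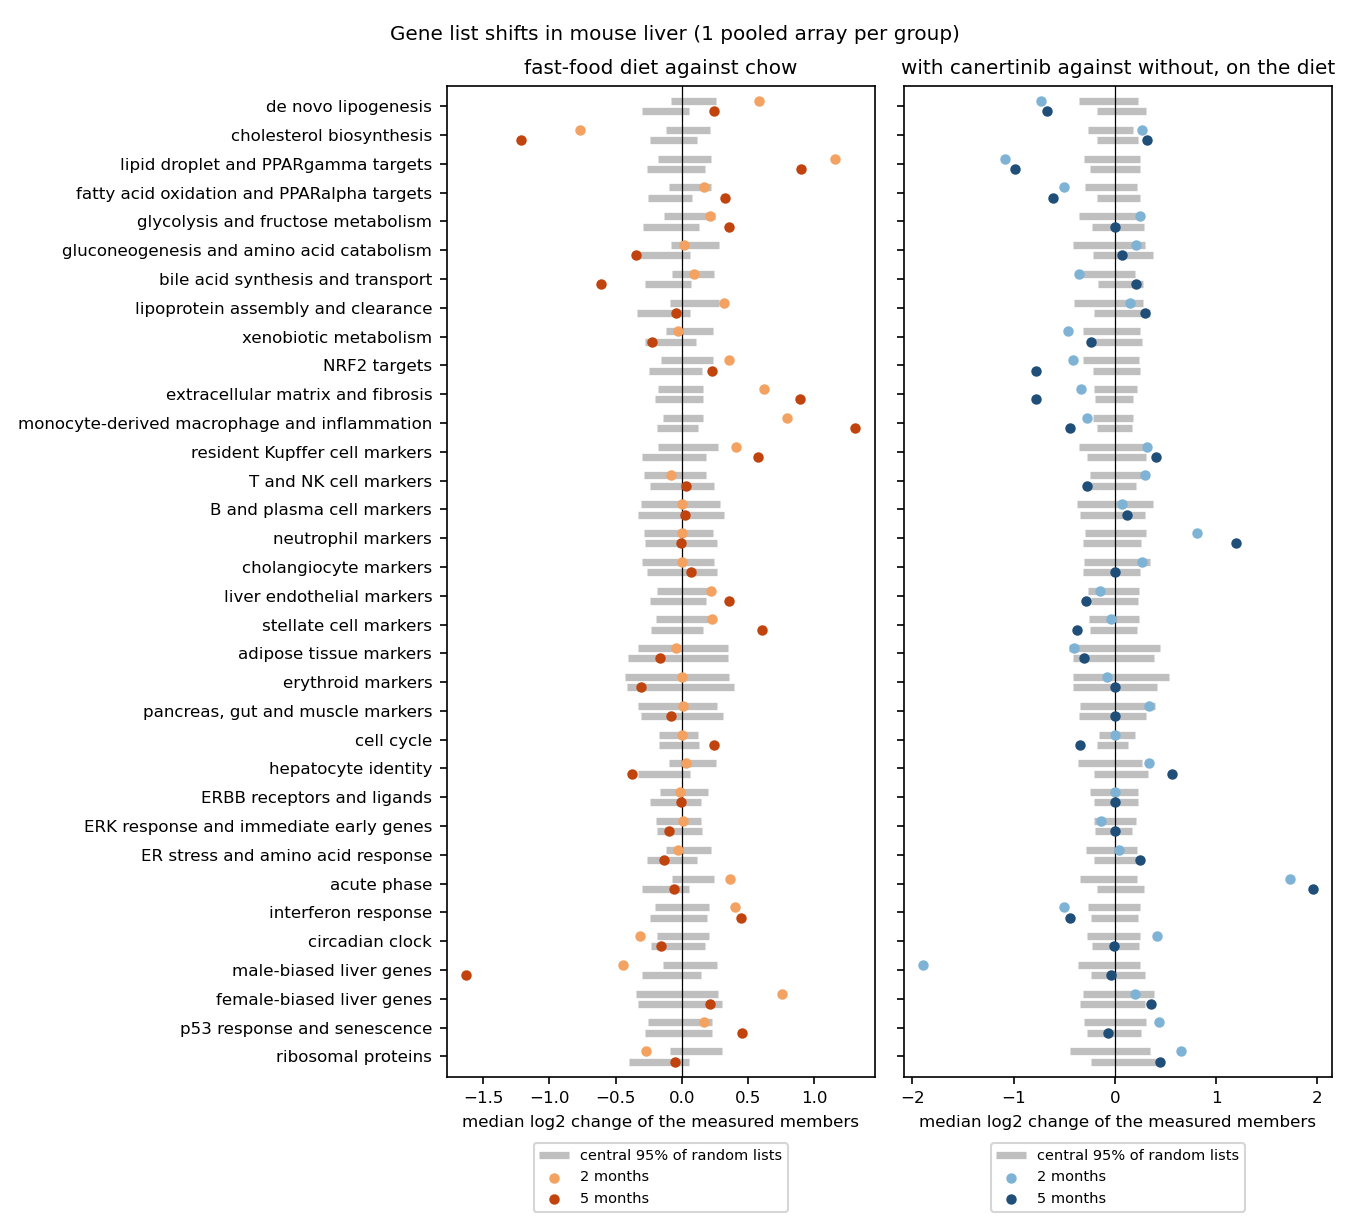
Median log2 change of the measured members of each of 34 gene lists, with the diet against chow (left) and with canertinib against without it (right), as points for 2 and 5 months beside grey bars for the central 95% of 10000 matched random lists. Lipid droplet genes lie at 1.16 and 0.90 with the diet and at -1.08 and -0.98 with the drug, and acute phase genes lie at 1.73 and 1.95 with the drug.

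The second question was how the liver transcriptome of mice on the fast-food diet differed with canertinib. At both times the drug-treated liver held more transcript of acute phase genes and neutrophil markers and less of genes for lipid storage, lipogenesis, fatty acid oxidation and extracellular matrix. The log2 difference between the 3' and 5' control probe sets of actin, a sign of RNA quality, was highest on the drug arrays, at 1.19 and 1.12 against 0.85 and 0.98 with fast food and 0.94 and 0.85 with chow, so it moved with each of these gene groups. That of Gapdh was -0.20 and -0.14 on the drug arrays, which in each study lay between fast food (-0.30 and -0.22) and chow (-0.18 and -0.09). Lcn2, which encodes an iron-siderophore-binding acute phase protein, had log2 changes of 5.39 at 2 months and 3.93 at 5 months, and the serum amyloid gene Saa2 had 5.17 and 4.55. Me1, which supplies NADPH for fatty acid synthesis, had -2.67 and -2.27, and the intestinal-type fatty acid binding protein gene Fabp2 had -2.96 and -2.42. Egfr was higher, with log2 changes of 1.27 and 2.64 and that sign in 4 and 5 of its 6 probe sets, and none of the 10 other measured genes of the ERBB receptor and ligand list was at least 2-fold different, though 3 of them were at the floor on at least 1 of the arrays compared.

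Acute phase genes had medians of 1.73 and 1.95, and 15 and then 17 of 22 were at least 2-fold higher with none at least 2-fold lower. Other members with large differences were Orm2 with 4.90 and 4.53, the metallothionein genes Mt1 with 5.15 and 3.75 and Mt2 with 4.74 and 4.15, and the serum amyloid P gene Apcs with 3.54 and 3.30, and outside the list Fgl1, a hepatocyte-secreted fibrinogen-like gene, had 4.39 and 3.38. Neutrophil markers moved with them at medians of 0.81 and 1.20, with 4 and then 6 of 10 at least 2-fold higher. The calprotectin gene S100a8 was at least 21.6-fold higher at 2 months and 20.7-fold higher at 5 months, and the granule protein genes Ngp and Ltf had 1.98 and 1.72 at 2 months and 2.28 and 1.58 at 5 months. Resident Kupffer cell markers were also higher, at 0.32 and 0.41, with 3 and then 1 of 12 at least 2-fold higher, and the scavenger receptor gene Marco had 2.67 and 1.92. Ribosomal protein genes had medians of 0.65 and 0.45 and hepatocyte identity genes 0.34 and 0.57, with Hnf4a, a master regulator of hepatocytes, at 0.67 and 1.03.

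Lipid droplet and PPARgamma target genes had medians of -1.08 and -0.98, with 8 of 16 at least 2-fold lower at each time and 2 and then 1 at least 2-fold higher. Cidec was at the floor on both drug arrays, with bounds of -1.96 and -3.26, and Cd36 had -1.60 and -0.90. Lipogenesis genes had -0.72 and -0.67, with 7 and then 6 of 21 at least 2-fold lower and 1 higher at each time, and Fasn had -1.78 and -1.06 and Elovl6 -1.39 and -1.16, whereas Scd1 had 0.14 and 0.27. Fatty acid oxidation and PPARalpha target genes had -0.51 and -0.61, with 8 of 26 at least 2-fold lower at each time, among them the peroxisomal genes Acaa1b with -4.81 and -1.91 and Ehhadh with -1.98 and -1.97. Cholesterol biosynthesis genes were higher, at 0.27 and 0.32, with 3 of 20 at least 2-fold higher at each time, and Idi1 had 1.67 and 1.16 and Sqle 1.44 and 1.03. NRF2 targets had medians of -0.42 and -0.78 with 5 of 15 at least 2-fold lower at each time, and Gclc, which encodes a subunit of the rate-limiting enzyme of glutathione synthesis, had -2.48 and -1.40. Xenobiotic metabolism genes had -0.46 and -0.23, with the epoxide hydrolase gene Ephx1 at -1.89 and -1.74.

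Extracellular matrix genes had medians of -0.33 and -0.78, and 5 and then 7 of 26 were at least 2-fold lower with none at least 2-fold higher, among them Col3a1 with -2.00 and -2.31, Col1a1 with -1.54 and a bound of -2.27, and Sparc with -1.10 and -2.11. Macrophage and inflammation genes had -0.27 and -0.44, but only 4 and then 6 of 29 were at least 2-fold lower and 2 were higher at each time. The lower members included the antigen presentation genes H2-Aa with -2.16 and -2.34 and Cd74 with -2.03 and -1.95, while Lgals3 had 0.42 and -0.67. Interferon response genes had -0.51 and -0.44 with 3 and then 1 of 14 at least 2-fold lower. Stellate, endothelial and cell cycle lists stood apart at 5 months alone, at -0.37, -0.28 and -0.35, and had -0.04, -0.15 and 0.00 at 2 months. The cyclin D1 gene Ccnd1 had -1.66 and -1.11.

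Among the 34 lists, the medians at the 2 times lay farthest apart for male-biased genes, whose median was -1.89 at 2 months, with 9 of 15 at least 2-fold lower, and -0.03 at 5 months, with 1 lower and 2 higher. The fatty acid hydroxylase gene Cyp4a12a had a bound of -5.03 and a value of -2.16, and the elongase gene Elovl3 had -3.84 and -0.66. Female-biased genes had medians of 0.20 and 0.35, the latter standing apart, and the steroid hydroxylase gene Cyp17a1 had 3.05 and 3.38. Bile acid genes had -0.35, which stood apart, and 0.21, which did not, and the bile acid 12alpha-hydroxylase gene Cyp8b1 had -3.68 and -1.99 while Cyp7a1, the rate-limiting enzyme of the pathway, had 1.20 and 1.63. Circadian clock genes stood apart at 2 months with 0.42 and not at 5 months with -0.01, and p53 response genes likewise with 0.43 and -0.07. Glycolysis genes had 0.25 and 0.01 and lipoprotein genes 0.15 and 0.30, and neither list stood apart. Single-time differences were large for Car3 with -5.82 and -1.32, the carboxylesterase gene Ces1f with -4.46 and -1.32, and the hepcidin gene Hamp with -4.72 and 0.01. The differences between the times were not tested.

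With the drug, 497 genes were at least 2-fold higher and 456 lower at 2 months, and 307 and 382 at 5 months. This balance turned under other scalings, with 451 and 474 at 2 months after quantile normalization and 346 and 337 at 5 months after median centring. The times, which share no array, had 133 higher genes in common where independent lists would have 10.9, and 121 lower genes where they would have 12.5. With the drug the fit over both studies called 57 higher and 43 lower genes at an adjusted p under 0.05 in limma, among them Orm2, Apcs, Lcn2, S100a8, Me1, Fabp2 and Col3a1, and 159 of the 254 shared genes were not called. Among the shared lower genes were Ces2e with -2.98 and -2.48, the galectin gene Lgals1 with -2.91 and -2.82, the fatty aldehyde dehydrogenase gene Aldh3a2 with -2.61 and -2.22 and S100a10 with -2.32 and -2.06. In the diet and drug comparisons together, 10 lists stood apart in none of the 4, with medians from -0.40 to 0.34, namely gluconeogenesis and amino acid catabolism, T and NK cells, B and plasma cells, cholangiocytes, adipose tissue, erythroid cells, pancreas, gut and muscle, ERBB receptors and ligands, ERK response, and ER stress. Only the B and plasma cell, erythroid and ERK lists among these also stayed within the limits of the 4 comparisons under every alternative. Calls that ended under other settings at 2 months were those of hepatocyte identity genes under 5 of 12 alternatives (quantile and loess normalization among them), bile acid genes under 3, and macrophage, Kupffer, NRF2, xenobiotic, ribosomal, circadian and p53 genes under 1 each. At 5 months they were those of female-biased genes under 4, Kupffer, ribosomal and xenobiotic genes under 3 each, and NRF2, hepatocyte identity and endothelial genes under 1 each. Lists that came to stand apart with the drug were, at 2 months, adipose and female-biased lists under 4 each, glycolysis and pancreas, gut and muscle lists under 2 each and cholangiocyte markers under 1. At 5 months they were ER stress genes under 4, T and NK cell and bile acid lists under 3 each, and ERBB, adipose and lipoprotein lists under 1 each.

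**Figure D2:**
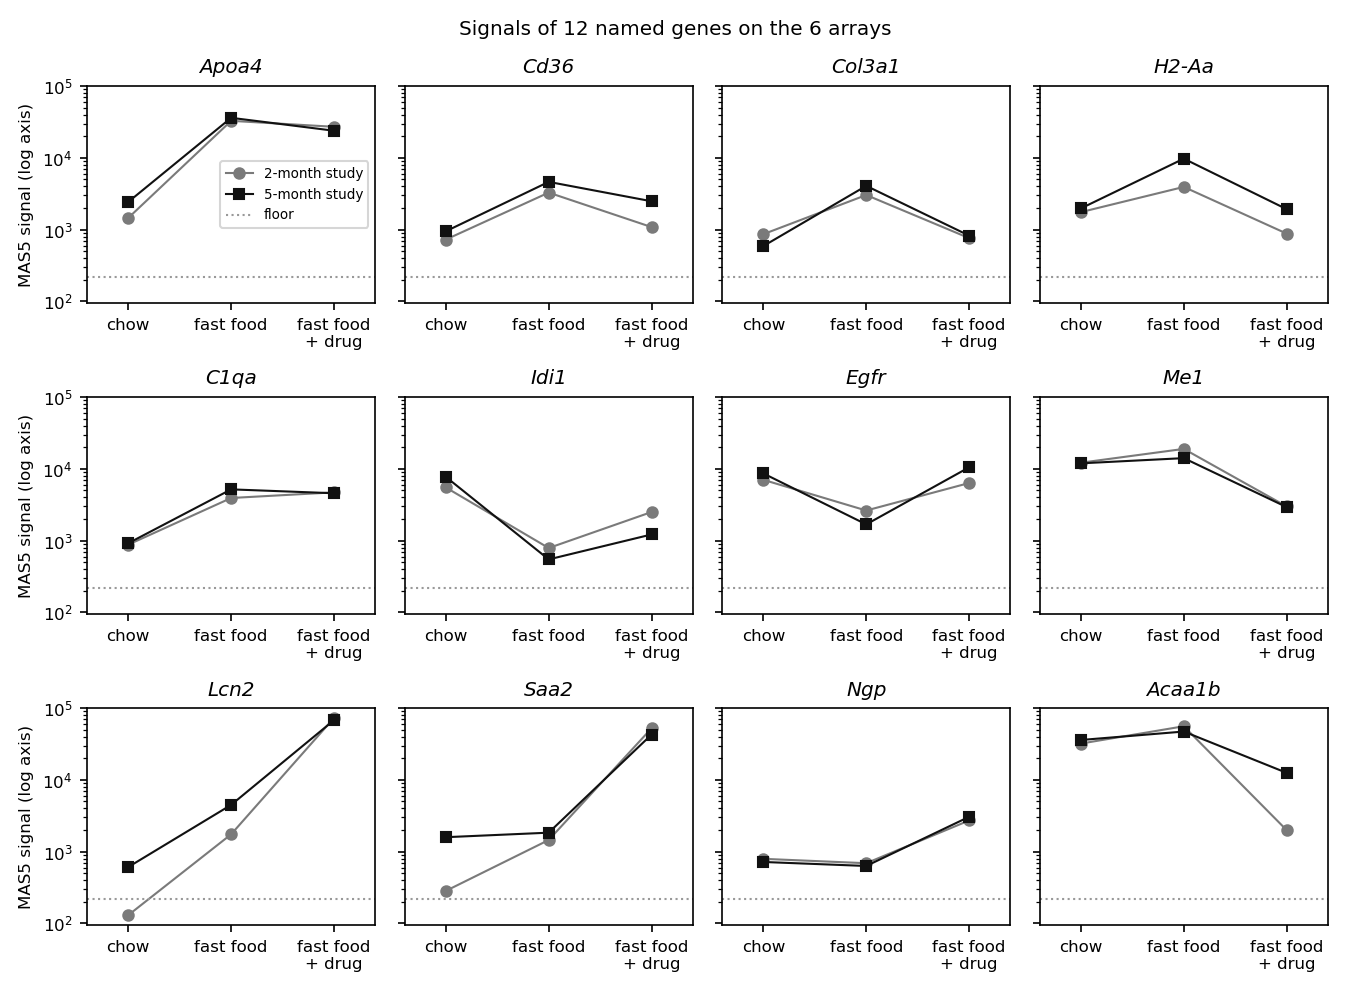
Signal of 12 named genes on the 6 arrays, on a log axis, with circles for the 2-month and squares for the 5-month study, lines joining the groups of a study (1 pooled array each) and a dotted line at the floor of 221.4. Cd36, Col3a1 and H2-Aa are higher with fast food than with chow and lower again with the drug, Egfr and Idi1 run the other way, C1qa stays high with the drug, and Lcn2, Saa2 and Ngp are highest with the drug.

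The last question was where the drug-treated fast-food liver lay relative to chow. Lipogenesis genes did not stand apart from chow in the drug-treated liver under any setting. Lipid storage and matrix lists did not with the settings used throughout but did under some alternatives. Acute phase, neutrophil, Kupffer and macrophage lists lay above and male-biased and cholesterol genes below chow. Lipid droplet genes had medians of 0.00 at 2 months and -0.11 at 5 months, but 3 and then 4 of 16 members were at least 2-fold higher than on chow and 3 and then 2 lower. Lipogenesis genes had -0.19 and -0.04, with 2 of 21 at least 2-fold higher at each time and 1 and then 2 lower, and matrix genes had 0.12 and 0.00, with 3 of 26 higher and 0 lower at each time. Matrix genes stood apart above chow under 2 of 12 alternatives at each time, and lipid droplet genes under 1 at 2 months and 2 at 5 months, where 2 others put them below chow. Apoa4 remained higher than on chow with log2 changes of 4.22 and 3.30, and Egfr had -0.15 and 0.28. Acute phase genes lay at 2.27 and 2.15, neutrophil markers at 1.43 and 1.02, Kupffer markers at 1.22 and 1.37, macrophage genes at 0.36 and 0.77 and glycolysis genes at 0.50 and 0.48, all standing apart. Cholesterol genes lay at -0.50 and -1.19, fatty acid oxidation genes at -0.34 and -0.41 and male-biased genes at -2.53 and -1.70, which also stood apart. Interferon response genes had -0.06 and 0.04 and did not. Further lists stood apart at 2 months alone, namely lipoprotein genes at 0.59, p53 response genes at 0.68, female-biased genes at 0.85, hepatocyte identity genes at 0.38, pancreas, gut and muscle markers at 0.42 and adipose markers at -0.44. At 5 months alone they were bile acid genes at -0.36, xenobiotic genes at -0.46, ER stress genes at 0.23 and ribosomal genes at 0.31. Under alternatives run for this comparison after the data were seen, calls at 2 months ended for pancreas, gut and muscle markers under 6, hepatocyte identity genes under 5, lipoprotein and adipose lists under 2 each and p53 genes under 1. At 5 months they ended for ER stress and bile acid genes under 2 each and ribosomal genes under 1. Lists that came to stand apart most often at 2 months were xenobiotic genes under 5 and cholangiocyte markers under 4. At 5 months they were stellate markers under 6, cholangiocyte markers under 5, lipid droplet genes under 4 (2 above and 2 below chow), and female-biased and p53 genes under 3 each. In this comparison 531 genes were at least 2-fold higher and 383 lower at 2 months, and 395 and 380 at 5 months, and limma called 78 higher and 29 lower genes over both studies at an adjusted p under 0.05.

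Diet and drug comparisons of the same study share the fast-food array, which alone makes their changes run in opposite directions, so they were also paired across the studies. Of the 494 genes at least 2-fold different with the diet at 2 months, 276 (55.9%, Wilson 95% interval 51.5 to 60.2, covering counting error over genes, which are not independent) had the opposite sign with the drug at 5 months. For the 637 diet genes of 5 months against the drug at 2 months, the count was 338 (53.1%, 49.2 to 56.9). Among measured genes that changed at all in both comparisons, the shares with opposite signs were 52.8% and 50.8%. Diet genes without any change with the drug were counted as not opposite, so these shares have an unlike base. Of the genes higher with the diet at 2 months, 56 were at least 2-fold lower with the drug at 5 months, where independent lists would share 7.6, and 17 were again higher, where they would share 6.1. For the diet at 5 months and the drug at 2 months, the counts were 54 against 12.4 and 38 against 13.5. Genes lower with the diet at 2 months and at least 2-fold higher with the drug at 5 months numbered 23 against 4.8, and 11 were again lower, against 5.9. In the other pairing these counts were 35 against 9.1 and 30 against 8.3. Both directions thus exceeded the independent counts, and the correlation across genes, which are not independent replicates, was -0.10 and -0.03.

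**Figure D3:**
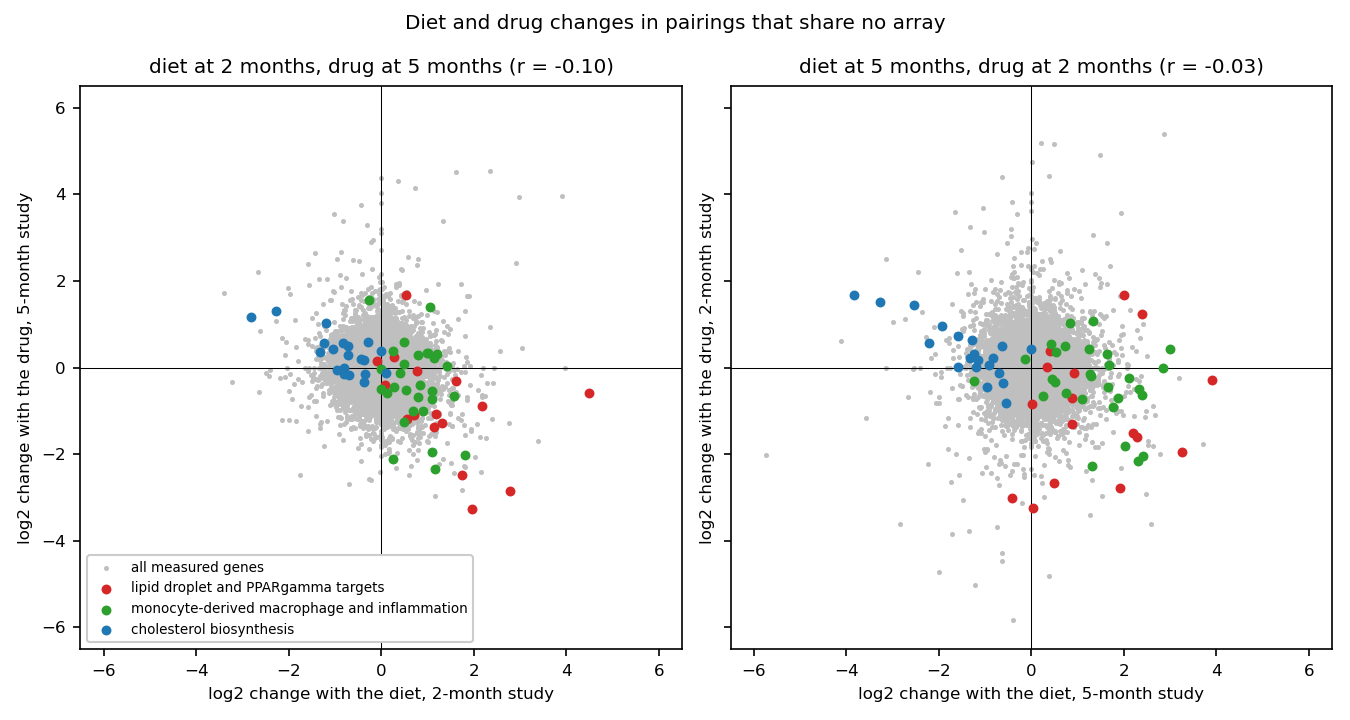
Log2 change of each of 13989 genes with the diet (horizontal axis) and with the drug (vertical axis) in the 2 pairings that share no array, with 3 gene lists in colour. The correlation over all genes is -0.10 and -0.03, and many lipid droplet genes lie to the lower right and cholesterol biosynthesis genes to the upper left.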

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

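The tests of blood in the pools, of neutrophil numbers and of opposite shifts of gene lists were chosen after the results were seen, and the other tests of this part before. Named genes that went in opposite directions at the 2 times, by at least 2-fold each, were looked at again, and none of these differences between the times was tested. The sialyltransferase gene St3gal6 had a log2 change with the diet of 3.90 at 2 months and -4.12 at 5 months, and the 2-month value was -0.13 without probe sets that may match other transcripts, and the chow arrays themselves differed by 2.67. With the drug, Abcd2 had -1.01 and 1.31, Hsd3b5 -2.02 and 1.73, both bounds with 1 array at the floor, and Slco1a1 -2.23 and 1.13. In probe sets outside the main measurement, 1 of 4 control probe sets for pyruvate carboxylase was 1.51 log2 higher on its highest treated array than on the higher chow array, where the other 3 had 0.99, 0.71 and 0.60. For transferrin receptor 1 of 3 had a bound of 1.93, with both chow arrays at the floor, and the others were below the floor on all arrays and so not measured. The signal of that 1 was 845.8 on the 2-month drug array against 144.5 and 177.2 on the chow arrays. Of 5039 measured probe sets without a single listed gene, 5.50% were at least 2-fold different with the drug at 2 months, against 2.42% between the chow arrays. The same shares of the measured genes were 6.81% and 2.60%, so these probe sets did not stand out.

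Acute phase genes and neutrophil markers were higher with the drug at both times. Scaling of the arrays is argued against, since the acute phase medians were 1.72 and 1.92 after quantile normalization. Whether the drug-treated livers held more neutrophils stays open, since the count of 8 of 10 neutrophil markers higher at both times only restates the pattern. Blood carried in the pools cannot be excluded, because red cell markers had medians of -0.0805 and 0.00 but only 1 of 5 lay more than 1 log2 unit above the floor on every array, and Alas2 had -0.84 and -0.30 while Slc4a1 had bounds of 1.08 and 0.46. An effect of the drug, an infection or an inflammatory reaction to dosing stays open and was not tested.

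Male-biased genes were lower with the drug at 2 months and not at 5 months. Scaling is argued against, since the medians were -1.87 and -0.11 after quantile normalization. For the list as a whole, so is a signal already near the floor at 5 months. Its genes lay a median of 2.93 log2 units above the floor on the 5-month fast-food array. That median does not cover single members, and Hsd3b5 was at the floor on that array. A female liver in the 2-month drug pool is argued against by Xist, taken for this test outside the rule for named genes, which differed by 0.12, while the Y-linked median of -0.11 rests on 3 genes that went both ways. With fast food and no drug these genes were already at -0.45 at 2 months and -1.63 at 5 months, and with drug and diet against chow at -2.53 and -1.70. Route, duration of dosing and age differed together between the studies, so which of them could lie behind the difference cannot be told from these arrays, and a biological difference stays a hypothesis.

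Within a study, genes at least 2-fold different with the diet had the opposite sign with the drug in 75.5% and 78.6% of cases. The share was 65.3% and 66.1% among genes that changed at all in both comparisons, whereas diet genes unchanged with the drug counted as not opposite. Correlations were -0.37 and -0.42, and covariances were -0.095 and -0.101. In simulated unchanged groups that share the fast-food array the values were -0.50 and -0.073. For unchanged arrays of equal noise, -0.50 follows by construction, so it does not show that the observed opposition was weaker. The simulated noise was taken from the chow pair, whose arrays also differ in age and study. Across studies, where no array is shared, the correlations were -0.10 and -0.03, so over all genes the opposition may come from the shared array, and -0.11 and -0.04 after loess normalization leave an intensity trend undecided. Counted over all lists that stood apart with the diet, 10 of 16 and 9 of 17 stood apart the opposite way with the drug across studies and 3 and 4 the same way, and the bound of 3 times as many was met in the first pairing and missed in the second, after which the lists were split into core and other lists. Among core lists 5 of 5 and 6 of 7 were opposite (macrophage genes, counted here, no longer stood apart with a higher floor) and 0 the same way, which a shared array could not give where none is shared, and among other lists 5 of 11 and 3 of 10 were opposite and 3 and 4 the same way, which decides nothing. Because the split followed the first count, an opposite effect of drug and diet on lipid, sterol, matrix and macrophage genes stays a hypothesis that these arrays cannot settle.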

How the results depend on the processing

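The alternative that leaves out genes differing between the chow arrays, the limma fit with study as a block and all alternatives for lists of the drug-treated liver against chow were chosen after seeing the data, and the others before. In place of the 145 and 254 genes shared by the studies, that fit called 4 genes with the diet and 100 with the drug at an adjusted p under 0.05. For core lists, 329 of 336 recomputed medians were the same, 6 came to stand apart, 1 no longer did and 0 reversed. A list that stood apart counted as the same if it kept its direction and its side of the limits. A list within the limits counted as the same if it stayed there, whatever its sign, so its sign changes are not among the reversals. Glycolysis genes with the drug at 5 months, for example, ran from -0.17 to 0.05 and counted as the same. For other lists 1205 of 1296 were the same, 37 came to stand apart, 46 no longer did, 7 moved and 1 reversed, and for named genes 7673 of 7896 were the same, 220 moved and 3 reversed. These lists are those of the 4 diet and drug comparisons, and for the drug-treated liver against chow 747 of 816 medians were the same, 46 came to stand apart, 19 no longer did, 2 moved and 2 reversed. No normalization moved a count of genes by over 1.5 times, but with the drug the balance of higher and lower genes turned at 2 months with quantile (451 and 474) and loess normalization (468 and 478) and at 5 months with median centring (346 and 337). For the chow pair it turned with every normalization, the mean over probe sets and the 3-fold threshold. With the drug it also turned at 2 months with the floor at the 60th percentile (331 and 348) and with genes above the floor on all arrays (313 and 320), and at 5 months at 3-fold (86 and 76). For the diet at 2 months it turned without a floor (706 and 743). For drug-treated against chow at 5 months it turned with the floor at the 40th percentile (588 and 598), without a floor and at 1.5-fold. Counts depended on floor and threshold, as a floor by construction acts on dim genes and a lower threshold by construction counts more genes. With higher and lower genes also counted apart, 13 of 29 counts and shares moved with the floor at the 40th percentile, 9 at the 60th, 20 with genes above the floor on all arrays and 1 with the mean over probe sets (lower genes of the chow pair, 114 against 185), and the overlaps moved in none of these.

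Counts are given in the order diet at 2 and 5 months, drug at 2 and 5 months, drug-treated against chow at 2 and 5 months, and the chow pair. Without a floor they were 1449, 1462, 1976, 1624, 1897, 1788 and 1190, with overlaps between the times of 343 for the diet and 514 for the drug. At 1.5-fold they were 2034, 2241, 3007, 2445, 2899, 2651 and 1712, with overlaps of 521 and 859, and at 3-fold 100, 161, 244, 162, 252, 197 and 44, with overlaps of 39 and 82. With genes above the floor on all arrays alone they were 288, 403, 633, 445, 579, 503 and 181. A floor at the 40th percentile gave 893 for the diet at 2 months, 1056 for the drug at 5 months, 1186 for drug-treated against chow at 5 months and 670 for the chow pair. A floor at the 60th percentile gave 312 for the diet at 2 months and 184 for the chow pair. The share of 2-month diet genes opposite with the drug at 5 months was 61.2% with the floor at the 60th percentile and 63.5% with genes above the floor on all arrays.

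With the floor at the 60th percentile, the macrophage and inflammation median with the drug at 2 months was -0.17 and no longer stood apart. Glycolysis genes came to stand apart at 2 months, with the diet at 0.28 with genes above the floor on all arrays and at 0.28 with chow-differing genes left out, and with the drug at 0.35 with the mean over probe sets. Against unmatched random lists, medians stayed as they were and stood apart for fatty acid oxidation with the diet at 2 months at 0.17 and for glycolysis with the diet at 0.21 and the drug at 0.25, both at 2 months. The xenobiotic metabolism median with the drug at 5 months reversed to 0.0016 with genes above the floor on all arrays. With shared and cross-matching probe sets left out, reversals were Ighm with the drug at 5 months at -0.35 against 1.46, Lyz1 with the diet at 5 months at -0.26 against 3.20, and St3gal6 with the diet at 2 months at -0.13 against 3.90, where another probe set then stood for the gene. In the drug-treated liver against chow, lipid droplet genes came to stand apart at 0.35 at 2 months and -0.31 at 5 months without a floor, and at 5 months at -0.31 with the floor at the 40th percentile, 0.49 with genes above the floor on all arrays and 0.42 with the mean in place of the median. Matrix genes did so at 2 months at 0.23 without a floor and 0.24 with the mean, and at 5 months at 0.38 with genes above the floor on all arrays and 0.27 with the mean. At 2 months hepatocyte identity genes reversed to -0.0620 with quantile normalization, and pancreas, gut and muscle markers to -0.12 with genes above the floor on all arrays. For the other changes the cause was not tested.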

Other observations

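No test was run in this part, and Tfrc, Igfbp1, Socs3 and Stat3 were chosen after their values were seen. Hamp, the gene of the iron hormone hepcidin, had signals of 42511 on 2-month chow, 29290 on fast food and 1115 with the drug, and 39497, 9881 and 9956 in the 5-month study. Tfrc, the transferrin receptor gene, had log2 changes with the drug of 2.17 and 1.30 on top of 1.14 and 1.38 with the diet. Hamp is known to be induced by inflammatory signals, and its signal was lowest on the array with the highest Lcn2 signal.

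Socs3, a feedback inhibitor of cytokine receptors, had a bound of 3.04 and a value of 1.97 with the drug, and Stat3 had 1.45 and 1.01. Igfbp1, an insulin-repressed gene of the liver, had 3.57 and 2.51 with the drug after 0.80 and 1.95 with the diet. The cell cycle inhibitor gene Cdkn1a had 1.81 and 0.51.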
